A study of Homo sapiens with 28 samples.

How the data were processed

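RNA-seq was analysed from 6 libraries of A549 cells, 3 with APE1 knockdown and 3 with the NTC control hairpin, grouped by the sample titles. Per the labels' protocols, cells carrying inducible hairpins received 2 µg/mL doxycycline for 3 days, total RNA was purified with a Qiagen kit and sequenced on an Illumina HiSeq. The 22 occupancy samples of the series are not analysed here.

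The deposited values are FPKM, fragments normalised to gene length and library size, computed by the authors for 48162 Ensembl genes with 1 column per library. The submitters' processing notes name STAR, DESeq2 and the builds GRCh37 and hg19, with no version and no role. The counting tool, annotation release, strand setting and the denominator of the FPKM are not given in the sources used here. All columns of the table matched a sample. FPKM are not counts, so no count model was used. The total of fragments cannot be read from them. Low values moved in steps: over at least 4420 genes below 0.5 FPKM in all libraries, between 65.9% and 68.2% of the ratios between a library and knockdown replicate 1 were ratios of whole numbers up to 6 within 0.5%, against at most 3.7% with a wrong step. This gave relative denominators of the FPKM between 1.00 and 1.16, which are relative depths only if the denominator is the library's total of fragments.

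Gene symbols came from a table pairing Ensembl IDs with symbols, which matched 33626 of the 48162 IDs. Biotypes and older symbols came from the RefSeq annotation of GRCh38.p14, of which no coordinates were used because the values are on another build. Of 670 entries in 28 gene lists, 668 matched a symbol. The lists, the tests and the rule for named genes were fixed before the data were examined.

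Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), and p-values were adjusted by Benjamini-Hochberg over 12537 genes, with a call at an adjusted p under 0.05. Lists with at least 5 tested members, 24 in all, were tested with limma's camera at a preset correlation of 0.01, with p-values adjusted over the lists, and again with an estimated correlation and with fry. Adjustment over the list alone used the limma p-values of its members. On simulated data with 12612 genes for this comparison, noise was independent between genes, and 100 genes each were changed by 0.5 or 1 on the log2 scale. Of those changed by 0.5, 76% were called, and of those changed by 1, 98%, and 5 of 179 calls were false. In the real data 25.4% of genes were called and genes may move together, so these rates may not carry over.

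Named genes were APEX1, the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes with a symbol, no overlap between groups and a mean of at least 5 FPKM in 1 group, leaving out Y-linked genes and XIST, and up to 4 members per list with the smallest adjusted p. Some genes that this rule takes are not reported here. Further members named in the text were chosen after their values were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

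Alternatives were other pseudocounts, filters and scalings, eBayes without trend or with robust, array quality weights, the replicate number as a block, stricter thresholds, and fits that left out each library in turn. After the data were seen, a scaling without mitochondrially encoded genes and a covariate for short transcripts were added. A planned test of G4 motifs in promoters was not run, since no genome was used here. Genes under 1 FPKM on average were left out of the tests, and 3 libraries per group limit the precision.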

Results

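The series maps abasic sites, DNA repair proteins and G-quadruplex (G4) structures along the genome and, in a separate arm, measures RNA after depletion of the repair enzyme APE1. APE1, encoded by APEX1, cuts DNA at abasic sites during base excision repair and also acts as a redox factor on transcription factors. Of the 28 samples, 22 are occupancy samples and are not analysed here. The other 6 are RNA-seq libraries of A549 cells, a human lung adenocarcinoma line with inducible short hairpin RNAs. In 3 libraries the hairpin targets APE1 and in 3 it is the control hairpin labelled NTC. All 6 received 2 µg/mL doxycycline for 3 days. Values are FPKM for 48162 Ensembl genes. The sum of FPKM per library was between 375461 and 395917, which is not a read count, and the absolute depth is unknown. Steps between low values put the denominator of the FPKM between 1.00 and 1.16 times that of knockdown replicate 1. This is the relative depth only if the denominator is the library's total of fragments. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

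The RNA comparison asks which genes depend on APE1. APEX1 (ENSG00000100823) itself was listed at 10.6, 12.6 and 13.1 FPKM in the knockdown libraries and at 152, 147 and 141 FPKM in the controls. The mean was 12.1 ± 1.29 FPKM (SD, n = 3) against 147 ± 5.67 FPKM (SD, n = 3), or 8.22% of the control mean. The log2 fold change was -3.56 with a standard error of 0.075 (limma adjusted p = 2.82e-08). Genes next to APEX1 on the chromosome did not follow it. Of 7 measured neighbours, 1 rose, CCNB1IP1 with a log2 fold change of 0.24, and none fell (camera adjusted p = 0.793). The CCNB1IP1 call was lost in 5 of the 6 fits that left out 1 library, with an adjusted p of up to 0.0943 without control replicate 1, and 2 neighbours rose without knockdown replicate 3.

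**Figure D1:**
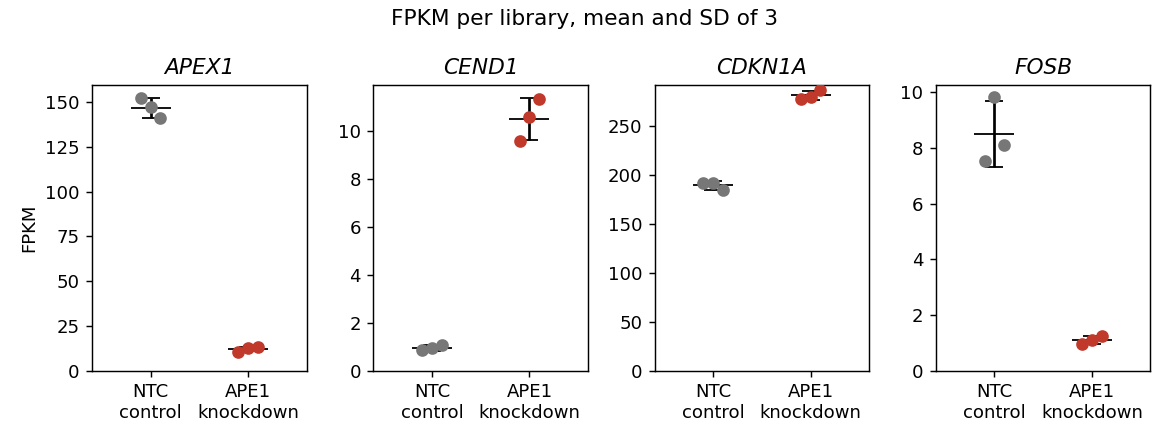
FPKM of APEX1, CEND1, CDKN1A and FOSB on linear axes from 0, with 1 point per library, grey for NTC control and red for APE1 knockdown; horizontal lines and bars give the mean and SD of 3 libraries. APEX1 lies between 10.6 and 13.1 FPKM in the knockdown libraries and between 141 and 152 FPKM in the controls.

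Many transcripts changed, most of them modestly. Of 12537 genes tested, 3188 passed an adjusted p of 0.05 in limma, 1400 of them higher and 1788 lower in knockdown cells. The median absolute log2 fold change of these genes was 0.36, and 22 higher and 75 lower genes changed by at least 1 on the log2 scale. The lower share of calls was 56.1%, and 67.0% after each library was rescaled to the same sum, with 1030 higher and 2093 lower genes. The knockdown and control values did not overlap in 5456 genes, or 43.5%, where chance gives 10%. The number of calls was 1910 without control replicate 3.

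The gene with the steepest rise among the well measured ones was CEND1, a neuronal protein linked to cell cycle exit, at 10.5 ± 0.879 against 0.952 ± 0.117 FPKM (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.097, limma adjusted p = 5.74e-07). SLC13A2, a sodium-coupled dicarboxylate transporter, rose by 1.88. The microRNA host transcript MIR23AHG rose by 1.26, the galectin gene LGALS2 by 1.14, the chemokine gene CCL2 and the angiotensinogen gene AGT by 1.03 each, and the transcription factor gene KLF2 by 1.02. MYO1A, a brush border myosin, PIP, and PDZK1, a scaffold of membrane transporters, rose by 1.00, 1.00 and 0.97. MZT2B and the antisense transcript POC1B-AS1 also passed the test, at 1.05 and 1.04, but their libraries were uneven. MZT2B was at 37.3 FPKM in knockdown replicate 3 and at 13.0 and 14.4 FPKM in the others, with adjusted p up to 0.0977 without control replicate 1. It shares sequence with MZT2A, so its value is uncertain. POC1B-AS1 lost its call in 4 of 6 fits with 1 library left out, with adjusted p up to 0.103 without control replicate 2, and the strand setting of the counting is not given in the sources used here.

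The gene with the steepest fall among the well measured ones was ARC, which dropped from 13.1 ± 2.71 to 0.584 ± 0.0477 FPKM (SD, n = 3 each), a log2 fold change of -3.62 (SE 0.141, limma adjusted p = 1.53e-06). Apart from the target APEX1, FOSB followed with -2.48, EGR1 with -2.26 and the small GTPase gene GEM with -1.84. TMEM30A, a subunit of phospholipid flippases, fell by 1.55 on the log2 scale. FURIN, the proprotein convertase of the Golgi, went from 149 ± 6.35 to 52.6 ± 0.895 FPKM, or 35.2% of control. BHLHA15 (MIST1), a transcription factor of secretory cells, changed by -1.59, and the endoplasmic reticulum (ER) genes CRELD2 and SDF2L1 by -1.39 and -1.38. SERPINB7 was at -1.74 and S100A8 at -1.42.

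p53 target genes rose as a group. Of 30 measured, 20 rose and 1 fell, with a median log2 fold change of 0.29 (camera adjusted p = 3.34e-08; adjusted p = 0.0746 with an estimated correlation). Adjusted over the list alone, 22 rose and 1 fell. CDKN1A, the p21 cell cycle inhibitor, went from 189 ± 4.31 to 281 ± 4.82 FPKM (SD, n = 3 each), a log2 fold change of 0.57 (limma adjusted p = 4.13e-05). SESN2 and TP53I3 rose by 0.58 each, DDB2 by 0.73 and FAS by 0.59, and PLK2 fell by 0.59. Without knockdown replicate 3, 2 members fell.

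Genes of DNA replication moved the other way. Of 24 S phase genes, 15 fell and 1 rose, counts that were the same adjusted over the list alone, with a median of -0.37 (camera adjusted p = 1.63e-05; adjusted p = 0.0746 with an estimated correlation). CDT1 and CDC6, which license replication origins, changed by -0.59 and -0.65, the primase gene PRIM1 by -0.70 and the thymidine kinase gene TK1 by -0.42. TYMS, thymidylate synthase, rose by 0.68. G2 and mitosis genes did not pass as a list, with a median of -0.08 (camera adjusted p = 0.534). Of 25 members, UBE2C rose by 0.28 and none fell, and the same count came from the list alone; without knockdown replicate 2, 4 fell, and without knockdown replicate 3, 1. CCNB1 at -0.22 and CENPF at -0.26 missed the threshold (limma adjusted p = 0.0593 and 0.0606). Replication-dependent histone genes rose, 6 of 11 and none lower, again the same over the list alone, with a median of 0.28 (camera adjusted p = 0.000511; adjusted p = 0.194 with an estimated correlation). Among them H2AC6 rose by 0.66 and H2BC21 by 0.56. H1-4, H1-5 and H3C4 were below the filter on low values and not tested. Their means were lower in knockdown, at 0.374, 0.0204 and 0.128 against 0.636, 0.122 and 0.322 FPKM in controls.

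The genes of ER and integrated stress split into opposite directions. Of 26 members, 10 rose and 12 fell, both over all genes and adjusted over the list alone. Among those that fell were CALR by 0.98, PDIA4 by 0.90 and PDIA6 by 0.69 on the log2 scale, and HSPA5 (BiP) by 0.67 and HSP90B1 by 0.64, the last 2 named after their values were seen. CALR went from 378 ± 11.7 to 191 ± 9.34 FPKM (SD, n = 3 each; limma adjusted p = 4.92e-06). The serine synthesis genes PSAT1 and PHGDH rose by 0.57 and 0.49, and CHAC1, TRIB3 and ASNS, known targets of ATF4, by 0.51, 0.39 and 0.31. ATF4 itself was at 0.05 (limma adjusted p = 0.458). The list's median was 0.04, its mean -0.18 and the direction of the camera test down (adjusted p = 0.565), so the signs differ. In the heat shock list 5 of 17 rose and 3 fell, over all genes as over the list alone, with a median of 0.00 and a mean of -0.02 while camera pointed up (adjusted p = 0.969). HSPD1, DNAJA1 and HSPH1 fell by 0.89, 0.54 and 0.36. HSPE1, which shares a promoter region with HSPD1, rose by 0.53, but its SD was 7.42 FPKM in the knockdown libraries, it has many processed pseudogenes, and its adjusted p was 0.0584 without control replicate 2. None of the heat shock genes rose without control replicate 1 or 2.

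Immediate early and inflammatory genes changed in both directions. Of 22 AP-1 and immediate early genes, 11 fell and 5 rose, or 12 and 5 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.00911; adjusted p = 0.681 with an estimated correlation). Besides FOSB and EGR1, DUSP6 and FOS fell by 0.75 and 0.73, while KLF2 rose by 1.02, JUND by 0.40 and JUN by 0.37. The higher members numbered 3 without control replicate 1 and 2 without control replicate 3. The list call was also lost among genes of at least 5 FPKM (camera adjusted p = 0.0654). NF-kB and inflammatory genes went both ways, 8 up and 9 down of 19 by either adjustment, with no call for the list (median -0.20, camera adjusted p = 0.565). The chemokine genes CCL20, CXCL1 and CXCL8 fell by 1.09, 0.75 and 0.62 and PTGS2, which encodes cyclooxygenase, by 0.74. CCL2 rose by 1.03 and RELB by 0.62. The higher members numbered 5 without control replicate 1 and 4 without control replicate 2 or 3. Of 16 interferon response genes, ISG20 rose by 0.64 and 4 fell, IFI6 and OAS3 among them at -0.65 and -0.53 (median -0.12, camera adjusted p = 0.389). Adjusted over the list alone, 1 rose and 5 fell, and 2 rose without knockdown replicate 2 or 3.

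Mesenchymal and matrix genes fell, 12 of 18 with 3 higher by either adjustment, at a median of -0.33 (camera adjusted p = 0.000106; adjusted p = 0.0777 with an estimated correlation). TGFBI, a secreted matrix protein induced by TGF-beta, went from 408 ± 7.54 to 170 ± 4.73 FPKM (SD, n = 3 each), a log2 fold change of -1.26 (limma adjusted p = 8.83e-07). TGFB2 fell to 43.3% of its control mean, and SNAI1 and CCN2 changed by -0.96 and -0.70. The 2 measured fibroblast markers, FBLN1 and COL1A1, fell too, by 0.55 and 0.49. The higher members numbered 1 without knockdown replicate 2 or control replicate 1, and 0 without control replicate 2 or 3. Epithelial junction and keratin genes showed no common direction, 4 up and 7 down of 18 by either adjustment (median -0.16, camera adjusted p = 0.199). CDH1, the E-cadherin gene, fell from 77.0 ± 1.19 to 38.5 ± 1.53 FPKM (limma adjusted p = 3.61e-06). CLDN2 fell by 0.60, while KRT81 and CLDN1 rose by 0.41 and 0.43.

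**Figure D2:**
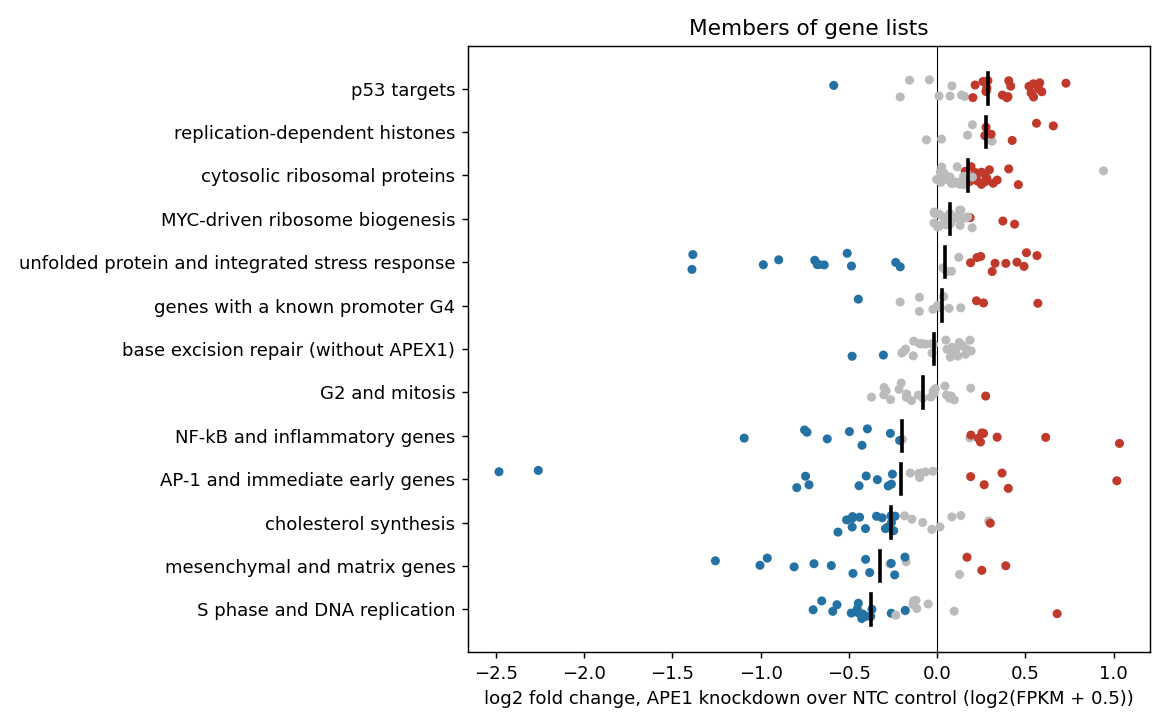
Log2 fold change of each measured member of 13 gene lists, APE1 knockdown over NTC control on the log2(FPKM + 0.5) scale; red and blue points are members that passed the test higher and lower, grey points did not pass, and black bars are list medians. p53 targets lie mostly above 0 with a median of 0.29 and S phase genes mostly below 0 with a median of -0.37.

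Ribosomal protein transcripts rose slightly. Of 38, 18 rose and none fell, or 23 adjusted over the list alone, at a median of 0.17 (camera adjusted p = 3.34e-08; adjusted p = 0.0992 with an estimated correlation). Genes of small subunits outside the ribosome, a group chosen after the values were seen, had 21 higher and 1 lower of 72 and a median of 0.15 (camera adjusted p = 4.45e-07; adjusted p = 0.238 with an estimated correlation). RPS23, RPLP1 and RPS19 rose by 0.46, 0.41 and 0.27. The number was 11 without control replicate 1 and 9 without control replicate 2 or 3. It was 6 with quantile normalization, where the median was 0.084, and 4 with no filter on low values. These genes have many near-identical pseudogenes, so their values are uncertain, and the pseudogene class itself had a median of 0.16 over 192 genes, though transcribed pseudogenes had 0.01 over 150. MYC-driven ribosome biogenesis genes had 3 higher and 0 lower of 24 by either adjustment, with a median of 0.08 (camera adjusted p = 0.0108; adjusted p = 0.31 with an estimated correlation). NOP16, NOP58 and RRP12 rose by 0.44, 0.37 and 0.19, of which RRP12 lost its call in 4 of 6 fits with 1 library left out (adjusted p up to 0.101 without control replicate 3). The higher members numbered 5 without knockdown replicate 3.

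Cholesterol synthesis genes fell, 15 of 24 with 1 higher by either adjustment, at a median of -0.26 (camera adjusted p = 0.000116; adjusted p = 0.103 with an estimated correlation). HMGCS1, DHCR7 and MVD, enzymes along the pathway, changed by -0.48, -0.48 and -0.56. The lower members numbered 9 without control replicate 3. NRF2 targets went both ways, 6 up and 7 down of 28 by either adjustment (median -0.01, camera adjusted p = 0.636). AKR1B1, an aldose reductase, fell from 1427 ± 28.3 to 877 ± 20.9 FPKM, PIR by 0.49 and HMOX1, heme oxygenase, by 0.32 on the log2 scale, and OSGIN1 rose by 0.52. The higher members numbered 3 without control replicate 2 or 3. HIF1 targets had 3 higher and 6 lower of 27 by either adjustment (median -0.09, camera adjusted p = 0.304). SLC2A1, the glucose transporter GLUT1, and ENO1 rose by 0.34 and 0.23, and HK1 and PFKFB3 fell by 0.40 and 0.24. The lower members numbered 2 without control replicate 1 or 3, and 3 without knockdown replicate 1 or 2 or control replicate 2.

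Nuclear-encoded respiratory chain genes had 3 higher and 5 lower of 26 by either adjustment (median 0.03, camera adjusted p = 0.974). UQCRC2, SDHA and NDUFV1 fell by 0.44, 0.33 and 0.22. The higher members numbered 5 without knockdown replicate 1 and 1 without any of the control libraries in turn. Mitochondrially encoded transcripts varied among the knockdown libraries. They took 1.98% of FPKM in knockdown replicate 1, 4.04% and 4.65% in replicates 2 and 3, and between 2.92% and 3.22% in the controls. None of 13 passed limma, over all genes or over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.431). MT-ND3, MT-ATP6 and MT-CYB were at 0.41, 0.37 and 0.33, and MT-ATP8 at 1.11 with an adjusted p of 0.102. Without knockdown replicate 1, 12 of the 13 passed as higher, with a list median of 0.49 (camera adjusted p = 1.43e-09; adjusted p = 0.361 with an estimated correlation). These genes move nearly as one, with an estimated correlation of 0.889 in that fit.

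Other genes of base excision repair changed little. Of 27, none rose and 2 fell, NEIL2, a DNA glycosylase, by 0.48 and the flap endonuclease gene FEN1 by 0.30 (list median -0.02, camera adjusted p = 0.974; 1 lower adjusted over the list alone). FEN1 lost its call in 4 of 6 fits with 1 library left out (adjusted p up to 0.119 without control replicate 3), and 4 genes rose without knockdown replicate 3. UNG at -0.18 and HMGB1 at 0.16 did not pass (limma adjusted p = 0.0632 and 0.0674). Of 22 double-strand break repair and Fanconi genes, TP53BP1 fell by 0.52 and FANCI by 0.33 and none rose (median -0.04, camera adjusted p = 0.534; 1 lower adjusted over the list alone). FANCI had an adjusted p of up to 0.101 without control replicate 1, and the lower members numbered 4 without knockdown replicate 2 and 1 without knockdown replicate 1 or control replicate 1 or 3.

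Of 14 measured genes with a known promoter G4, 3 rose and 1 fell, by either adjustment (median 0.03, camera adjusted p = 0.534). CDKN1A, PDGFA and HRAS rose by 0.57, 0.26 and 0.22 and HIF1A fell by 0.45. Calls of PDGFA and HRAS were lost without some libraries, with adjusted p up to 0.0789 and 0.0768 without control replicate 3, and 1 gene rose without control replicate 1 or 3. MYC, whose promoter G4 is among the best studied, had 92.3 ± 1.49 FPKM in knockdown and 93.9 ± 5.62 FPKM in control libraries (SD, n = 3 each), a log2 fold change of -0.02 (SE 0.054, limma adjusted p = 0.782). VEGFA was at 0.04 (limma adjusted p = 0.761). MYC and VEGFA were named after their values were seen. Of 18 G4 helicases and binding proteins, 1 rose and 2 fell by either adjustment, the latter ERCC2 by 0.30 and KDM1A by 0.17, while the helicase gene DHX9 was at -0.12 (list median 0.01, camera adjusted p = 0.969). Calls of ERCC2 and KDM1A were lost without some libraries, with adjusted p up to 0.0785 without control replicate 3 and 0.112 without control replicate 1. In this list 2 genes rose without knockdown replicate 3 or control replicate 2, and 0 without control replicate 3.

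Few markers of other cell types reached a mean of 1 FPKM. Of 13 fibroblast markers, 2 had a mean of at least 1 FPKM, FBLN1 and COL1A1, which fell as given above; COL1A1 had an adjusted p of up to 0.087 without control replicate 3. Of 16 haematopoietic markers 2 were measured, CD14, which fell by 1.15, and CD8A at -0.07. The members tested change when a library is left out. LYZ passed the filter when any 1 knockdown library was left out, and fell. HBB passed it without control replicate 2, where it rose by 0.69. It also passed the filter without control replicate 3, where it was at 0.96 and not called (limma adjusted p = 0.0541). The filter is on the mean of the libraries left in, so leaving out a library lets in genes that are low in it. The directions of LYZ and HBB thus follow in part from the filter. Of 14 neural and endothelial markers 4 were measured, of which RBFOX3 and MAP2 fell by 0.47 and 0.32, or 1 higher and 3 lower adjusted over the list alone. MAP2 lost its call in all 6 fits with 1 library left out (adjusted p up to 0.151 without control replicate 1). Of 12 embryonic kidney markers 4 were measured. None of these passed, over all genes or over the list alone, and 0 had an unadjusted limma p under 0.05. Lung alveolar markers, which suit the origin of the line, had 5 of 17 measured, so by this share they did not stand out from the kidney markers. ABCA3 was higher by 0.23 and CAV1 and LPCAT1 lower by 0.30 and 0.24, by either adjustment (camera adjusted p = 0.701). ABCA3 and LPCAT1 had adjusted p up to 0.0745 without control replicate 3 and 0.0862 without control replicate 1.

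Of 24 lists tested, 8 passed the camera test with the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Correlation between members is not the only reason for this loss. For S phase and mesenchymal genes the estimated correlations were -3.25e-06 and -0.055, below the preset 0.01, and the calls were still lost. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, which weakens the test. With a covariate for short transcripts, chosen after seeing the data, the calls of immediate early genes, histones and MYC-driven genes were lost (camera adjusted p = 0.0735, 0.258 and 0.584), and with no filter on low values the interferon list passed as lower (camera adjusted p = 0.0111). Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes.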

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

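The scaling without mitochondrially encoded genes and the covariate for short transcripts were chosen after seeing the data. The log2 fold change of APEX1 kept its direction and its call under all alternatives, between -3.61 and -3.47 when 1 library was left out. The count of 3188 changed genes was 2065 with no filter on low values, where 28892 genes were tested, 1531 at an adjusted p under 0.01, 97 with an absolute log2 fold change of at least 1, and between 1910 (without control replicate 3) and 3245 (without knockdown replicate 3) with 1 library left out. With the short-transcript score of each library as a covariate it was 80, and the log2 fold change of HSPE1 turned to -0.075. The group explains 83.0% of that score's variance, so this fit has little left to estimate the knockdown with. The count of 8 lists was 0 with an estimated correlation (6 at an unadjusted p under 0.05 in limma's camera), 15 with fry, which does not compare a list with other genes, and 8 or 9 with 1 library left out. Of the 3188 calls, 95 changed sign with the added covariate and 0 under the other alternatives that tested them by another fit of limma. Rescaling each library to the same sum kept 2815 of the 3188 calls, and eBayes without trend 2619. With array quality weights 3986 genes passed. With the replicate number as a block 2269 genes passed and 8 lists did. The replicate numbers showed no sign of pairing: same-numbered libraries had correlations of -0.066, -0.158 and -0.086, and no sample correlated best with its own number. These correlations are of deviations from means of 3 libraries, which constrain each other, so they cannot exclude a shared culture or batch. Of 128 named genes other than APEX1, 104 passed, and 85 lost the call with the added covariate and 20 in at least 1 other alternative. The test of G4 motifs in promoters and its 5 alternatives were not run. The cause of the changes was not tested where none is given, and the absolute depth, which limits calls of low genes, is unknown.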

Other observations

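The groups in the next paragraph and all tests of explanations below, apart from the splits of the libraries, were chosen after the values were seen, so their p-values are not independent evidence.

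Genes of ER folding and quality control outside the fixed lists were lower in knockdown cells, 22 of 31 with 1 higher, at a median log2 fold change of -0.32 (camera adjusted p = 7.42e-11; adjusted p = 0.0472 with an estimated correlation). MANF, a secreted ER stress protein, changed by -0.99 (SE 0.060), and NUCB2 and HYOU1 changed by -1.02 and -0.71, while ERP29 rose by 0.33. Complement genes had 8 lower and 0 higher of 15 (median -0.27, camera adjusted p = 0.000107; adjusted p = 0.0472 with an estimated correlation), with C4BPA, C3 and CFI at -0.77, -0.74 and -0.63. Alcohol and aldehyde dehydrogenases had 12 lower and 0 higher of 18 (median -0.27, camera adjusted p = 4.49e-06; adjusted p = 0.0472 with an estimated correlation). With quantile normalization the adjusted p with an estimated correlation was 0.0514 for ER folding genes, 0.0514 for complement genes and 0.0669 for the dehydrogenases, so no call with an estimated correlation was kept. The medians were then -0.32, -0.26 and -0.28. The camera calls at the preset correlation were kept (adjusted p = 9.86e-12, 4.73e-05 and 1.78e-06). ALDH3A1 fell from 1090 ± 9.95 to 579 ± 49.1 FPKM and ADH1C from 13.9 ± 0.702 to 5.01 ± 0.175 FPKM. Aminoacyl-tRNA synthetase genes went up, 7 of 20 with 0 lower (median 0.11, camera adjusted p = 0.00256; adjusted p = 0.245 with an estimated correlation), among them SARS1 and GARS1 by 0.42 and 0.34. Amino acid transporters had 7 higher and 4 lower of 19 (camera adjusted p = 0.133), with SLC7A5 at 0.53 and SLC7A2 at -1.19. S100 genes had 4 higher and 4 lower of 12 (camera adjusted p = 0.719), and annexins 2 and 4 of 11 and serpins 3 and 5 of 17, each with a camera adjusted p of 0.55.

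Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real split, the real split itself with 3188. The highest of the other splits gave 0 in limma, with up to 455 genes at an unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached. The other splits mix knockdown and control libraries in both groups, so any real difference between the groups widens the spread and lowers the calls. Few calls there were to be looked for whatever the source of that difference.

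Ribosomal protein transcripts were slightly higher in knockdown cells, at a median of 0.17. The scaling of the FPKM may account for part of this: with quantile normalization the median was 0.084 and 6 members were called in place of 18 (camera adjusted p = 0.0167; adjusted p = 0.571 with an estimated correlation), so this stays open. Over 4 other scalings, quantile normalization included, the median lay between 0.084 and 0.181, and the list kept its camera call at the preset correlation in all 4. Apart from quantile normalization, these scalings multiply each library by 1 factor and so move all genes nearly alike. They can hardly change a test against the other genes, so their kept calls do not bear on this question. A different yield of short mRNAs between libraries may contribute: mRNAs of 72 small subunits outside the ribosome, which are known to be short though lengths were not measured here, had a median of 0.15, 21 higher and 1 lower (adjusted p = 0.238 with an estimated correlation), and those outside mitochondria and ribosome a median of 0.15 over 22 genes. Whether knockdown itself or library preparation raises these mRNAs stays open, because the group explains 83.0% of the variance of the short-mRNA score. That score is the median of the same 72 mRNAs, chosen after their values were seen, so its tie to the group is partly set by that choice.

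ER folding genes were lower in knockdown cells. The scaling of the FPKM is not borne out as the whole cause, since with quantile normalization the median was -0.32 and 22 were called lower (camera adjusted p = 9.86e-12; adjusted p = 0.0514 with an estimated correlation). A different yield of long mRNAs was not tested, because transcript lengths were not analysed here. Lower stress signalling as a whole was set against synthetase genes, known targets of ATF4, of which 7 were higher and 0 lower. Their lower quartile was 0.015, smaller in size than the median shift of -0.038 from rescaling the libraries to the same sum. As a group they had a camera adjusted p of 0.245 with an estimated correlation. They cover the ATF4 branch alone, and with quantile normalization 6 of them were higher and 0 lower. For these genes the values argue against lower signalling in that branch, and so against a fall of all branches. Whether the other branches fell stays undecided. What lowers ER folding genes stays open, since other groups such as complement genes and dehydrogenases were lower too, at medians of -0.27, and an effect of the hairpin apart from APE1 was not tested.

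S phase genes were lower at a median of -0.37 while p53 targets were higher. Repression of cell cycle genes through p53 and the DREAM complex, or fewer dividing cells, would lower G2 and mitosis genes too. Their median was -0.08, but their lower quartile of -0.20 reaches past -0.19, 0.5 times the S phase median, so these explanations cannot be told apart from an effect on S phase alone with these values. The scaling of the FPKM is not borne out as the whole cause, since with quantile normalization the median was -0.35 and 12 of 24 were called lower (camera adjusted p = 2.63e-05; adjusted p = 0.0731 with an estimated correlation, where the list is not called with the deposited values either).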
